A study of Oryza sativa with 7 samples.

How the data were processed

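The series measured G-quadruplex capture in rice seedlings by BG4 (2 libraries, with 1 input library as control) and BioTASQ (2 libraries, with 2 biotin libraries as control). The submitters' processing notes name Trim Galore 0.4.4, BWA, Picard, SAMtools 1.5, MACS2 2.1.1 and deepTools, without stating their order or settings. Each of the 4 deposited peak lists has the layout of a MACS2 peak file. In it the deposited score is the whole-number part of 10 times the -log10 p, the deposited fold enrichment is a ratio at the summit over the authors' control, and the deposited -log10 p and -log10 q belong to the peak. The lowest deposited -log10 p is just above 5. The other deposited columns are positions and the summit's offset in bp. Per the file headers the deposited motif tables give the position, strand, length, sequence and, for G3 motifs, a loop class, and the authors' BG4 interval of each motif; these are other units than counts. Neither file type gives read counts, so depth is unknown and no interval or floor from counting could be computed.

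All 60723 peak names of BioTASQ replicate 2 say replicate 3, and the sample label was followed. A pair of motif sheets of chromosome 2 have their G2 and G3 names exchanged, and the class was taken from the content. In the tables as used here 732 G3 lines (1.99%) and 3657 G2 lines (0.204%) held no entry and were passed over. 1251 G3 entries repeat a position, and all entries were counted. Start positions were read as 0-based and are printed as 1-based. The span of a chromosome is taken from the highest position in the files.

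Overlap and motif content of peaks were compared with 1000 random placements of the peaks on their own chromosome, widths kept, with a two-sided permutation p. The share of motifs in peaks was divided by the share under random placement, computed by formula. Consensus regions are merged regions of both replicate lists with a peak of each. Intervals are the 95% range of 1000 bootstrap draws of blocks of 1 Mb. They measure spread along the genome within fixed peak lists, not spread between replicates. Peak heights were compared by 100000 permutations within a list. Replicate numbers are 2 per assay, which cannot give an exact two-sided p below 0.333, so no test across samples was made. The assays also differ in material, buffer, capture reagent, control and sequencer, so a difference between them cannot be assigned to one of these. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used. The methods were tested on simulated data, where 96 of 100 bootstrap intervals held the true odds ratio. There each motif was drawn on its own within its block. Clustering of motifs in a peak and the intervals of contrasts, medians and small motif classes were therefore not tested.

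Named regions followed a rule adapted from one for genes that had been fixed before the data were examined. It takes, per assay, the 10 consensus regions with the highest fold in their lower replicate, and the 10 regions in all 4 lists with the best mean rank of fold. The adaptation was made after it was known that no annotation of the build was at hand. Shares in promoters and gene features, strand in promoters, gene groups, gene lists, the gene panel and placement matched on G+C content were planned and not run, since no genome or annotation of this build was used here. Alternatives fixed before the data were examined were the upper 50% of each list by -log10 p, peaks of 200 bp, equal numbers of peaks, rotation of all peaks, reciprocal overlap of 50%, peaks without G3 motifs, motifs wholly inside peaks, merged motifs, G2 motifs outside G3 motifs, each replicate list alone and 3 classes of peak width. Placement on G2 motifs, each position once, motifs of 1 copy without runs of 8 or more G, and peaks of 200 bp for the odds ratio were added after the data were seen. So were the 7 contrasts between motif classes, with their alternatives, and the classes by C content, G run, copies, telomere type and trinucleotide.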

Results

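Quadruplex-forming DNA of rice (Nipponbare, seedlings of about 2 weeks) was captured by 2 assays, both from seedlings fixed with 1% formaldehyde. BG4 is an antibody fragment that binds folded G-quadruplexes, and it was applied to fragmented genomic DNA that had been freed of cross-links, purified, denatured and refolded with potassium and polyethylene glycol. BioTASQ is a biotinylated small molecule that binds G-quadruplexes, and it was applied to fragmented chromatin before the cross-links were reversed. The series has 7 libraries, of which 2 are BG4, 2 are BioTASQ, 1 is an input and 2 are biotin controls. Each BG4 and BioTASQ replicate has its own peak list, and the 3 control libraries enter only through those lists. The lists held 48275 and 44001 BG4 peaks with median widths of 359 and 356 bp, and 45311 and 60723 BioTASQ peaks with median widths of 285 and 428 bp. They covered 5.59% and 5.12% (BG4) and 4.38% and 8.89% (BioTASQ) of the 373 Mb spanned on 12 chromosomes. Read depth behind the peaks is unknown. Predicted quadruplex motifs came from the deposited tables, with 36099 G3 motifs (tracts of 3 or more G) and 1793382 G2 motifs (tracts of 2 or more G). The genome build is not given in the sources used here, so positions are those of the deposited lists.

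The first question was whether the replicates of an assay captured the same places. In BG4, 67.5% of replicate 1 peaks overlapped a replicate 2 peak, 6.76 times the 10.0% found when peaks were placed at random on their chromosome. In the other direction 74.0% overlapped, 6.78 times random. In BioTASQ, 91.2% of replicate 1 peaks overlapped a replicate 2 peak (6.25 times random) and 60.7% of the longer replicate 2 list overlapped replicate 1 (5.78 times). With the same number of peaks in every list these BioTASQ shares were 79.0% and 69.5% (6.74 and 6.24 times), so their size depended on list length. All these had a permutation p of 0.002, two-sided, the smallest that 1000 placements can give. The fold moved with the definition of overlap, to 20.1 in BG4 and 17.7 in BioTASQ when 50% of both peaks had to be shared, and fell to 4.08 and 2.73 when peaks were placed on G2 motifs. The series has 1 input library for both BG4 lists, and random placement does not separate overlap that comes from a shared control from overlap in capture. Regions held by both replicates numbered 31955 for BG4 (median 499 bp) and 36807 for BioTASQ (median 564 bp), and are called consensus regions.

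The next question was whether quadruplexes folded in purified DNA and those captured from chromatin lay at the same places. Of the BG4 consensus regions 39.0% overlapped a BioTASQ consensus region, 3.19 times the 12.2% at random. Of the BioTASQ regions 32.9% overlapped a BG4 region, 3.14 times random. The permutation p was 0.002 in both directions, again the smallest possible. Between single lists the overlap ran from 26.5% (BG4 replicate 1 in BioTASQ replicate 1) to 53.6% (BG4 replicate 2 in BioTASQ replicate 2), below the overlap between replicates of either assay. Against placement on G2 motifs the excess was smaller, 1.51 times for BG4 regions and 2.08 times for BioTASQ regions. When 50% of both regions had to be shared, it was 5.97 and 5.99 times. Merging all lists gave 95521 regions, of which 12056 (12.6%) held a peak of every list, 13382 held peaks of both BG4 replicates and no BioTASQ peak, and 19631 held peaks of both BioTASQ replicates and no BG4 peak.

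**Figure D1:**
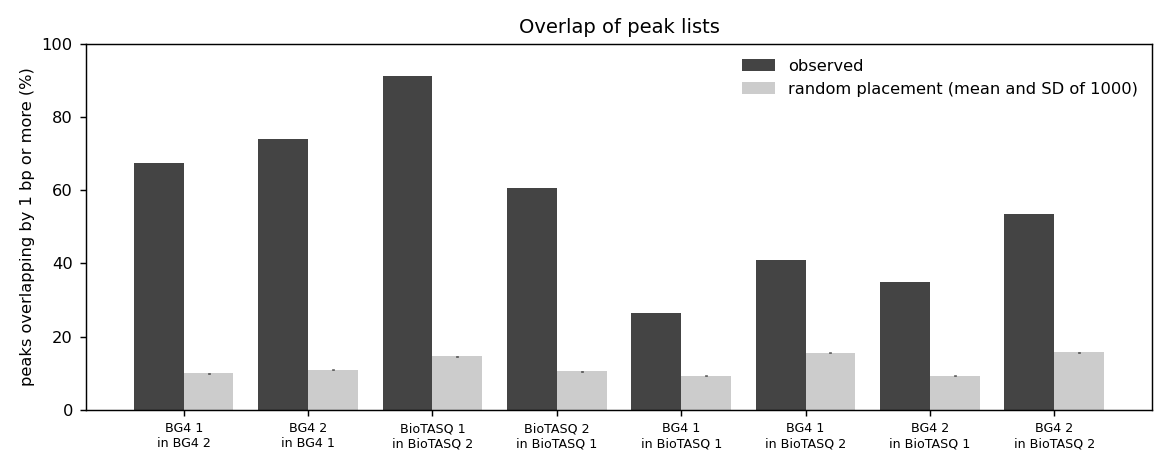
Percent of the peaks of one list that overlap a peak of another by 1 bp or more, observed (dark bars) and under random placement (light bars, mean and SD of 1000 placements). Replicates of an assay overlapped by 60.7% to 91.2%, lists of different assays by 26.5% to 53.6%.

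Over 368 windows of 1 Mb, peak numbers followed the assay. Pearson's r between replicates was 0.784 for BG4 (Spearman's rho 0.807) and 0.835 for BioTASQ (rho 0.791). Between the consensus regions of the assays r was 0.108 (rho 0.0766), and between single lists it ran from -0.0631 (replicate 1 of both) to 0.200 (replicate 2 of both), so its sign depended on the replicate. BG4 consensus regions had an r of 0.391 with G3 motifs and 0.149 with G2 motifs, but by r the order did not hold in both lists. It was 0.310 with G3 and 0.320 with G2 motifs in replicate 1, and 0.451 and 0.331 in replicate 2. By rho the order held in both, with 0.331 and 0.312 in replicate 1 and 0.440 and 0.319 in replicate 2. BioTASQ regions had an r of 0.254 with G3 and 0.316 with G2 motifs, in the same order in replicate 1 (0.223 and 0.251) and replicate 2 (0.338 and 0.516). These are correlations across windows, which are not independent replicates, for 24 pairs and without a test.

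The motif tables gave the next question, which motifs each assay captured. Of the BG4 consensus regions 23.7% held a G3 motif, 5.58 times the random 4.25%, and of the BioTASQ regions 13.1% did, 2.64 times the random 4.97%. Each list showed the enrichment, with 4.32 and 6.54 times in BG4 replicates 1 and 2 and 2.03 and 2.90 times in BioTASQ replicates 1 and 2. With consensus regions placed on G2 motifs instead of anywhere on the chromosome, the excess fell to 4.02 times in BG4 and 1.92 times in BioTASQ. G2 motifs were in 99.1% of BG4 regions (random 80.9%) and 99.9% of BioTASQ regions (random 83.0%). The permutation p was 0.002 for all 4, the smallest possible.

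Counted from the motifs, BG4 peaks held 35.1% ± 9.55 (SD, n = 2 lists) of G3 motifs and 10.4% ± 0.326 of G2 motifs. BioTASQ peaks held 17.4% ± 12.8 (SD, n = 2 lists) of G3 motifs and 19.8% ± 8.86 of G2 motifs. Over random, this was 6.33 ± 2.09 times for G3 motifs in BG4 and 2.36 ± 0.818 times in BioTASQ, and 1.84 ± 0.169 and 2.84 ± 0.0128 times for G2 motifs. Both BG4 lists lay above both BioTASQ lists for G3 and below both for G2, although 2 lists against 2 cannot go below an exact two-sided p of 0.333. The odds of lying in a consensus region were 4.78 times higher for G3 than for G2 motifs in BG4 (95% interval 4.64 to 4.94). This odds ratio was 6.03 without replicate 1 and 3.49 without replicate 2, both outside that interval. In BioTASQ the odds ratio was 0.885 (0.849 to 0.923), and its direction was not stable. It was 1.02 without replicate 1 (interval 0.988 to 1.07), 0.583 without replicate 2, and 1.10 both with overlapping motifs merged and with motifs of a single copy. The log2 ratio of the odds ratios, BG4 over BioTASQ, was 2.43 (interval 2.37 to 2.50).

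Around the summits of the peaks, G3 motifs were most frequent within 60 bp in BG4 and farther away in BioTASQ. A G3 motif lay on 1.43% and 2.74% of BG4 summits (replicates 1 and 2), against 0.300% and 0.318% at 900 to 1000 bp from them. The highest BG4 values were 60 and 40 bp away, and replicate 1 had a slight dip at the summit from 1.66% at -60 bp. The BioTASQ values were 0.415% and 0.687% at the summit against 0.388% and 0.391% in the flanks, and their profile dipped at the summit, with its highest values 280 and 140 bp away. G2 motifs peaked at the summits of all 4 lists, on 48.8% and 66.3% of BG4 summits and 62.3% and 66.0% of BioTASQ summits, against 20.6% to 23.4% in the flanks.

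**Figure D2:**
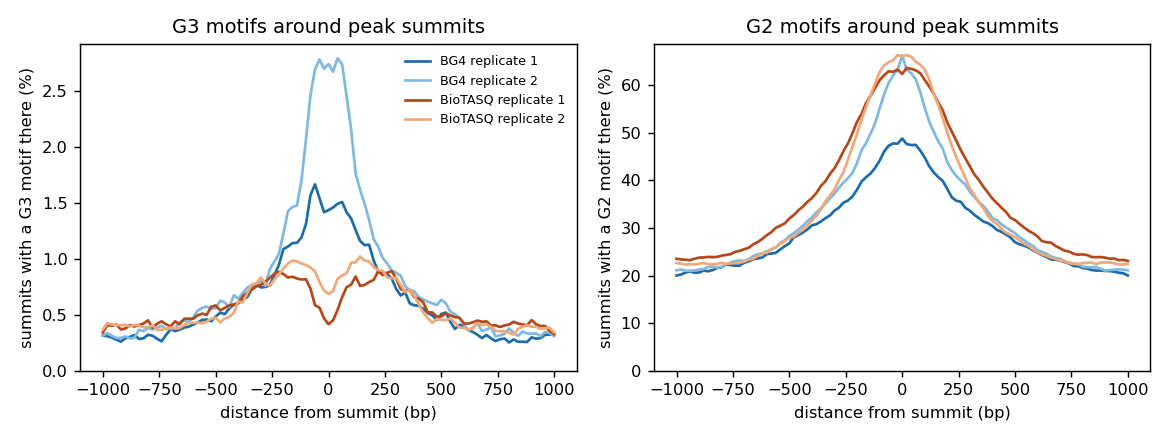
Percent of summits with a G3 (left) or G2 (right) motif at each distance in bp from the summit, one line per list. G3 motifs rose to 2.74% at BG4 replicate 2 summits, dipped at BioTASQ summits and dipped slightly at BG4 replicate 1 summits. G2 motifs rose at the summits of all 4 lists.

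Loop length is the class the deposited G3 table gives, and the longest class was captured more than the shortest in both assays. Motifs whose longest loop had 8 to 12 bases were in BG4 peaks 6.96 ± 2.34 times as often as at random and motifs with loops of 1 to 3 bases 5.26 ± 1.53 times (SD, n = 2 lists). The BioTASQ values were 3.06 ± 0.995 and 1.76 ± 0.584 times. BG4 capture was highest at loops of 6 to 7 bases in both lists, with a mean of 7.52 ± 2.88 times (SD, n = 2 lists). In replicate 1 the interval of that class (5.19 to 5.78) overlapped that of loops of 8 to 12 bases (5.15 to 5.48). BioTASQ capture was higher in each longer loop class in the consensus regions, from 1.79 to 3.44 times, and in replicate 2, from 2.18 to 3.77 times, although the intervals of the shortest classes (1 to 3 and 4 to 5 bases) overlapped. In BioTASQ replicate 1 it was 1.35 times at loops of 1 to 3 bases, 1.14 at 4 to 5, 1.74 at 6 to 7 and 2.36 at 8 to 12. On the log2 scale and over consensus regions, the long loops exceeded the short by 0.38 in BG4 (interval 0.34 to 0.43) and 0.94 in BioTASQ (0.86 to 1.02), and by 0.22 and 0.59 among motifs of a single copy without runs of 8 or more G. With peaks of 200 bp the BioTASQ value was 0.58. The difference of these, BG4 minus BioTASQ, was -0.56, -0.35 without replicate 1, and -0.15 with an interval that held 0 when every peak was set to 200 bp. G3 motifs in consensus regions had a median length of 36 bp against 31 bp outside in BG4 (37 against 29 bp without replicate 1), and 40 against 31 bp in BioTASQ. G2 motifs had 43 against 33 bp in BG4 and 39 against 32 bp in BioTASQ, with a median of 7 tracts against 5 in BG4 (6 against 5 without replicate 2) and 6 against 5 in BioTASQ.

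Long runs of G were captured less, most of all by BioTASQ. G3 motifs with a run of 8 or more G were at 3.02 ± 1.11 times random in BG4 and 0.271 ± 0.275 times in BioTASQ, and those whose longest run had 4 G at 7.20 ± 2.15 and 3.71 ± 0.845 times (SD, n = 2 lists). The log2 contrast of runs of 8 or more over runs of 4 was -1.23 in BG4 and -3.36 in BioTASQ, where it was -5.34 without replicate 2. Unbroken G runs lay in BG4 peaks in 12.4% ± 2.92 of cases and in BioTASQ peaks in 1.05% ± 1.27 (SD, n = 2 lists). Such runs hold no C, and all G3 motifs without C were at 1.19 ± 0.594 times random in BioTASQ (SD, n = 2 lists). Run length was not compared within classes of C content or loop length, so its share in these values was not separated from theirs.

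**Figure D3:**
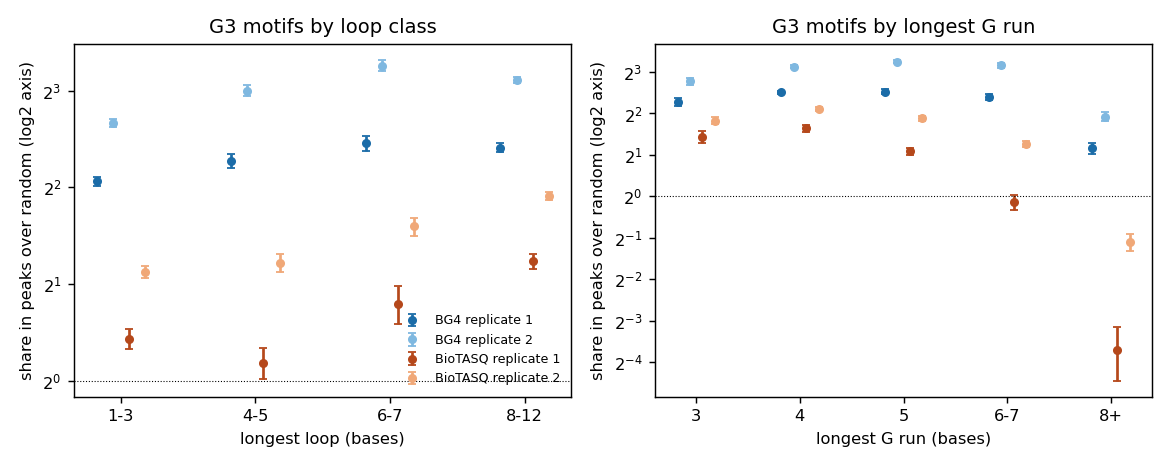
Share of G3 motifs in peaks over the share under random placement (log2 axis), by longest loop in bases (left) and longest G run in bases (right), one point per list with the 95% interval of the 1 Mb block bootstrap. At runs of 8 or more G the BioTASQ lists averaged 0.271 times random and the BG4 lists 3.02 times.

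The C content of the G-rich strand separated the assays. G2 motifs outside G3 motifs and without any C were at 2.20 ± 0.0662 times random in BG4 peaks and 0.726 ± 0.0994 times in BioTASQ peaks (SD, n = 2 lists). Those with above 30% C were at 1.26 ± 0.165 times in BG4 and 5.47 ± 0.235 times in BioTASQ. The log2 contrast of 20 to 30% C over no C was -0.27 in BG4 (interval -0.32 to -0.23, with -0.18 without replicate 1 and -0.44 without replicate 2) and 2.60 in BioTASQ (2.53 to 2.65). With single-copy motifs without runs of 8 or more G the BG4 value was -0.10 (interval -0.15 to -0.055). Among G3 motifs it was -0.12 in BG4, with an interval that held 0 without replicate 2 (-0.054) and a value of -0.26 without replicate 1, and 1.86 in BioTASQ. In BG4 it was -0.40 with peaks of 200 bp and -0.31 with single-copy motifs without runs of 8 or more G. In BioTASQ it was 1.82 and 1.61 in the same order. That contrast leaves out the other classes, in which BG4 capture of G3 motifs was 5.47 ± 1.99 times random without C, 7.21 ± 2.23 times at 10 to 20% C and 1.17 ± 0.324 times above 30% C (SD, n = 2 lists). BioTASQ capture of G3 motifs above 30% C was 4.69 ± 2.38 times (SD, n = 2 lists). Captured G2 motifs had a median C content of 24% in BioTASQ regions against 16% outside, and of 17% against 18% in BG4. G2 motifs with 4 units of GGT in a row were at 8.36 ± 0.40 times random in BG4 and 4.75 ± 0.137 times in BioTASQ, while those with 4 units of GGC were at 5.40 ± 0.586 and 5.35 ± 0.688 times (SD, n = 2 lists). Those with 4 units of GGA were at 7.12 ± 0.903 times in BG4 and 5.48 ± 0.60 times in BioTASQ (SD, n = 2 lists). The order of these repeats in BioTASQ depended on the list. GGC, GGA and GGT were at 5.83, 5.06 and 4.84 times in replicate 2 and at 5.53, 5.13 and 4.49 times in the consensus regions. In replicate 1 they were at 4.86, 5.91 and 4.65 times. The G runs, C classes and repeat units were chosen after the data were seen.

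**Figure D4:**
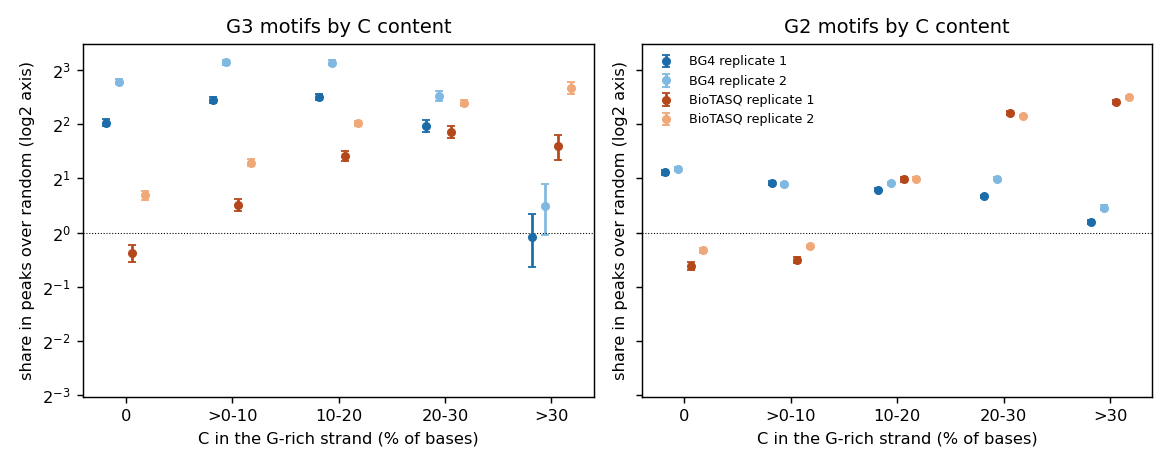
Share of G3 (left) and G2 (right) motifs in peaks over the share under random placement (log2 axis), by percent C of the G-rich strand, one point per list with the 95% interval of the 1 Mb block bootstrap. BioTASQ capture of G2 motifs rose from 0.726 times random without C to 5.47 times above 30% C, and BG4 capture went from 2.20 to 1.26 times.

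Peaks with a G3 motif were higher than peaks without a motif of either class in every list. The median log2 fold enrichment over the authors' control differed by 0.36 and 0.59 in BG4 replicates 1 and 2, and by 0.22 and 0.66 in BioTASQ replicates 1 and 2. The permutation p was 1e-05 in each list, two-sided, the smallest that 100000 permutations can give. Most peaks held G2 motifs alone. For peaks with a G3 motif, G2 motifs alone and no motif the median fold was 5.17, 4.41 and 4.04 in BG4 replicate 1. It was 6.11, 4.74 and 4.05 in BG4 replicate 2. In BioTASQ it was 4.00, 3.88 and 3.45 in replicate 1 and 5.18, 4.61 and 3.28 in replicate 2. Part of each difference was thus present without a G3 motif, and peaks with G2 motifs alone were not tested. Peaks without any motif were few, with 3020 and 695 in BG4 and 233 and 114 in BioTASQ. They were also narrower, and within 3 classes of peak width the differences were 0.15, 0.26, 0.075 and 0.33 in the same order, with a permutation p of 1.6e-04 in BioTASQ replicate 1 and 1e-05 in the others.

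The 10 BG4 consensus regions with the highest fold in their lower replicate had 1 with a G3 motif and 10 with a G2 motif, and 3 had no BioTASQ peak. The leading motif of a region is the one with the most tracts, taken among G3 motifs where there were any. In 8 of these regions it was over 300 bp long, a length chosen after the values were seen. The first, on chromosome 7 from 13366492 to 13367232, had fold enrichments of 20.7 and 20.2 and no BioTASQ peak, and held a G2 motif of 605 bp on the minus strand. The region on chromosome 9 from 2839888 to 2840294 had 35.2 and 20.0 and no BioTASQ peak, and held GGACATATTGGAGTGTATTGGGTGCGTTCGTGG, a sequence with 1516 copies in the motif tables, and whether its reads came from this place alone is unknown. The region on chromosome 3 from 11030825 to 11032725 had 24.0 and 18.4 in BG4 and 4.23 and 6.05 in BioTASQ, and held the G3 motif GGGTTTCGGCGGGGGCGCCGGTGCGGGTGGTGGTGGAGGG.

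Among the 10 BioTASQ consensus regions chosen the same way, 3 held a G3 motif and 10 a G2 motif, 6 had a peak in BG4 replicate 2 alone, 3 in both BG4 replicates and 1 in neither. The first, on chromosome 8 from 6944774 to 6945158, had fold enrichments of 13.3 and 16.9 in BioTASQ and 4.35 in BG4 replicate 2, and held a G2 motif of 161 bp. The region without a BG4 peak lay on chromosome 5 from 5051034 to 5051322, with 8.69 and 8.91 and a G2 motif of 156 bp. Of the 10 regions in all 4 lists with the best mean rank, 4 held a G3 motif. The first of these, on chromosome 4 from 34996927 to 34998531, had 12.6 and 13.3 in BG4 and 5.35 and 8.91 in BioTASQ, with 21 G2 motifs. The second, on chromosome 2 from 15995038 to 15996313, had 9.64, 12.6, 5.82 and 9.20 in the same order, and held the G3 motif GGGGGAGGGGGATTGGGCTGGGG.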

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

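All 7 contrasts between motif classes, and the tests of peak width, of identical copies with long G runs, of surrounding DNA on the difference between assays, and of absence of C in telomere-type motifs were chosen after the results were seen, as was the restriction of the length test to 42 motifs; the bounds of the other tests were written before their values were known.

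Each value here drew attention because the contrast differed between the assays by a bootstrap interval that excluded 0, and is BG4 minus BioTASQ on the log2 scale. G2 motifs with 20 to 30% C over those without C differed by -2.87, and G3 motifs by -1.98. Telomere-type G3 motifs over all G3 motifs differed by 3.35, with a lower bound of 1.67, which was 0.68 without replicate 1 of both assays (difference 2.37) and 2.11 without replicate 2 (difference 4.18). G3 motifs over G2 motifs outside them differed by 2.01. G3 runs of 8 or more G over runs of 4 differed by 2.12, and by 3.99 without replicate 2 of both assays. Loops of 8 to 12 over loops of 1 to 3 bases differed by -0.56, by -0.35 without replicate 1 of both assays, by -0.37 with single-copy motifs and by -0.15 with peaks of 200 bp, where the interval held 0. G2 sequences of 50 or more copies over 1 copy differed by 0.46, which was -0.23 without replicate 1 of both assays 2.02 without replicate 2 and 0.71 with peaks of 200 bp. The assays were run on different material with different reagents and controls, and no biological explanation was tested.

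For C content, peak width and repeated or long-run motifs were argued against as the whole cause, since the difference of -2.87 became -3.14 with peaks of 200 bp and -3.10 with single-copy motifs without long runs. The G+C content of the motif was argued against as the whole cause too, since the BioTASQ contrast within 5-point classes was 1.70 (interval 1.64 to 1.76) against 2.60 without matching, while the BG4 contrast went from -0.27 to -0.60. Surrounding DNA stays open for the BioTASQ side: within 5 classes of the motif coverage in 250 bp on each side the contrast was 1.28 (1.23 to 1.33), and the bound set beforehand was 1.30, which lies inside that interval. A second criterion, added after that undecided result, asked about the difference between assays, which was -2.44 (interval -2.51 to -2.37) because the BG4 contrast went from -0.27 to -1.17 as the BioTASQ contrast fell; matching moved both contrasts down, so surroundings may account for part of the BioTASQ contrast and offset part of the BG4 one, and they were argued against only as the whole cause of the difference. The G+C content of whole fragments was not measured.

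For telomere-type motifs, 84.3% of the 70 lay in BG4 peaks of each replicate and 1.43% and 10.0% in BioTASQ peaks. Length alone was argued against, since other G3 motifs without C, weighted to the lengths of the 42 that could be matched, were in BG4 regions at 37.9% (interval 30.6 to 44.8) against 73.8%; the longer ones had no match. Lying within 100 kb of a chromosome end was argued against as the whole cause, since other G3 motifs there were at 34.1% (25.4 to 43.9). Distance inside those 100 kb was not matched, so a place at the very end was not tested. The intervals in both comparisons are those of the other motifs, and the telomere-type shares of 73.8% and 84.3% were taken as fixed. The 70 motifs lay on 10 chromosomes and mostly near ends, so they are not 70 independent sites. Both comparisons are therefore less certain than their intervals show. Motifs with long G runs, which BG4 captured less, were not left out of either comparison. Still, 59 of the 70 lay at ends and each BG4 replicate captured 1 of the 11 in the interior, so sequence alone may not be enough either, and sequence, length and place stay entangled. Whether their low BioTASQ capture goes beyond the absence of C stayed open, with a log2 ratio of -1.25 and an upper bound of 0.41.

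For repeated G2 sequences, the 2 BG4 replicates differed, with 9.33% and 4.74% of motifs of 50 or more copies in peaks. Weak peaks near the threshold were argued against, since the log2 difference between replicates was 1.60 in the upper 50% of each list against 1.10 over all peaks. C content was argued against, since the difference within its classes was 1.10. Whether reads that map to several places were treated alike in both replicates was not tested. The BioTASQ replicates differed on these motifs too, in the other order, with 3.33% and 13.5% in peaks of replicates 1 and 2. Over random this was 0.728 and 1.51 times. Their log2 contrast of 50 or more copies over 1 copy was -2.22 in replicate 1 and -1.06 in replicate 2. A difference between replicates was thus not particular to BG4, and the explanations above were tested for BG4 alone.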

How the results depend on the processing

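The contrasts between motif classes with all their alternatives, placement on G2 motifs, each position once, peaks of 200 bp for odds ratios and single-copy motifs were chosen after the data were seen. Of 224 alternatives over 53 results, 213 stayed on their side of the threshold without reversing, 4 lost the threshold, 1 gained it and 6 reversed. A move to or from a difference of 0, which some medians made, was not counted as a reversal. All 84 alternatives of the placement results kept their direction and side of the threshold, with folds from 1.14 to 20.1, and so did all 4 of peak height. The BioTASQ odds ratio of G3 over G2 motifs reversed to 1.02 without replicate 1 (0.583 without replicate 2), to 1.10 with merged motifs and to 1.10 with single-copy motifs without long G runs. The BioTASQ log2 contrast of G3 over G2 reversed likewise, to 0.049 without replicate 1 (-0.67 without replicate 2) and to 0.12 with single-copy motifs. The assay difference for repeated sequences ran from -0.23 to 2.02 leaving out a replicate of each assay. The BG4 contrast of G3 motifs by C content ran from -0.26 to -0.054 leaving out a replicate, the latter short of the threshold, and was -0.40 with peaks of 200 bp and -0.31 with single-copy motifs. The assay difference for loop length was -0.15 with peaks of 200 bp, short of the threshold. In BG4 the median longest loop of G2 motifs differed by -1 to 0 leaving out a replicate, and their median C content by -1 to 0. For all of these the cause was not tested. No paired analysis was possible because BG4 and BioTASQ libraries share replicate numbers only and come from separate experiments. Placement matched on G+C content and every alternative for promoters, promoter strand and gene groups, the logistic models included, were not run. Unknown depth limits all peak lists, since a place without a peak may have lacked reads, and BioTASQ replicate 2 had 60723 peaks against 45311. With equal numbers of peaks the overlap of BioTASQ replicate 1 with replicate 2 was 6.74 times random, while its share fell from 91.2% to 79.0%.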

Other observations

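The sequences and intervals here were looked at after the data were seen, and no test of an explanation was made on them.

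The commonest G2 sequence of 20 bp or more, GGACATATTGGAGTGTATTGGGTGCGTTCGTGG, had 1516 copies, of which 50.8% and 8.97% lay in BG4 peaks of replicates 1 and 2 and 0 in BioTASQ peaks. The G3 sequence GGGGGGAAAGGGAGAGGGGATCACGGGG, picked for its high capture, had 118 copies, of which 45.8% and 97.5% lay in BG4 peaks and 0% and 55.1% in BioTASQ peaks of replicates 1 and 2. The G3 sequences with more copies (190, 190 and 157, unbroken G runs left out) lay in peaks at 0% to 3.68% in each list.

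The authors' deposited motif tables name a BG4 interval for 19.2% of G3 motifs and 3.46% of G2 motifs. These 21706 intervals had a median width of 322 bp, and 96.4% and 96.6% overlapped a peak of BG4 replicates 1 and 2. Within 100 kb of chromosome ends there were 109 BG4 and 92.1 BioTASQ consensus regions and 154 G3 motifs per Mb. In the distance classes farther from the ends there were 79.8 to 87.6 BG4 regions, 98.4 to 98.9 BioTASQ regions and 83.8 to 100.5 G3 motifs per Mb.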
